A study of Mus musculus with 43 samples.

How the data were processed

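Sciatic nerve RNA from 43 mice was profiled by 3′ tag sequencing with the Lexogen QuantSeq 3′ mRNA-Seq kit, per the labels' protocols. The mice were C22 animals, a transgenic model of Charcot-Marie-Tooth disease type 1A that carries human PMP22, and wild type littermates. Nerves were taken at 5 weeks of age without treatment, or at 15 weeks after 9 weeks of weekly subcutaneous injection of phosphate-buffered saline (PBS) or of an antisense oligonucleotide (ASO1) at 100 mg/kg, 2 days after the last dose. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14 and assigned to transcripts with Salmon 0.7.2, with the mouse build GRCm38.p4. The transcript index, read trimming and strand setting are not given in the sources used here.

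The deposited tables hold 92468 transcripts per library, each with an estimated count of reads and a TPM value. The deposited estimated counts are not whole numbers and are not normalized. The deposited TPM values are divided by transcript length, which a 3′ tag count does not grow with, so they were not used here. Of the transcripts, 90712 matched GENCODE mouse release M21, which gave gene names and coordinates, and 1756 did not and were left out. Estimated counts were summed over the transcripts of each of 31114 genes and rounded to whole numbers. Totals ran from 368784 to 6792960 estimated reads per library. The means were 3806000 ± 930500 (SD, n = 8) in c22 given ASO1, 4286000 ± 1738000 (n = 8) in c22 given PBS, 3821000 ± 1833000 (n = 8) in c22 at 5 weeks, 2491000 ± 1020000 (n = 8) in wild type given ASO1, 2693000 ± 666700 (n = 8) in wild type given PBS and 3402000 ± 1147000 (n = 3) in wild type at 5 weeks.

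Groups were taken from the labels: 8 libraries each of c22 at 5 weeks, c22 given PBS, c22 given ASO1, wild type given PBS and wild type given ASO1, and 3 of wild type at 5 weeks. The titles call the wild type PBS group a baseline, while the treatment field gives PBS, which was used. Title numbers run from 7258 to 7281 in c22 and from 8087 to 8105 in wild type, so any difference between runs goes with genotype. No pair of libraries had identical values. Over 143 pairs within groups, the chi-square per degree of freedom of the gene counts ran from 6.99 to 91.95, so every library was kept as its own replicate.

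The main test was edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr on the 6 groups (minimum count 10, minimum total 15), robust quasi-likelihood F-tests, two-sided, with all 43 libraries in a single fit with 37 residual degrees of freedom. It tested 14712 genes in 9 contrasts, with Benjamini-Hochberg adjustment within each contrast and calls at an adjusted p under 0.05. CPM values are TMM-scaled. Standard errors of log2 fold changes are from the same fit.

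In each contrast 22 gene lists fixed before the data were examined were tested with camera from limma 3.58.1, with a preset correlation of 0.01, adjusted over the 22 lists. The lists cover compact myelin, cholesterol synthesis, fatty acid synthesis, immature and injury-associated Schwann cells, non-myelinating Schwann cells, macrophages and phagocytes, lymphocytes, mast cells, interferon-stimulated genes, fibroblasts and extracellular matrix, adipocytes, skeletal muscle, endothelium, pericytes and smooth muscle, perineurial cells, neurons and axons, the cell cycle, the unfolded protein response, ATF4 targets, p53 targets, immediate early genes and red blood cells. The tests were repeated with an estimated correlation and with fry, which asks whether a list's genes move on balance in a single direction. Over the 9 contrasts camera called 51 lists, the estimated correlation 4 and fry 39. Members were called over all genes and adjusted over the list alone. The injury-associated and non-myelinating Schwann cell lists share Gfap, Ncam1, L1cam and Ngfr, so their results are not independent in any contrast.

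Named genes followed a rule fixed before the data were examined. It took Pmp22, then the 8 highest and 8 lowest log2 fold changes in c22 against wild type at 15 weeks and in ASO1 against PBS in c22, and 4 and 4 in the other contrasts. These came from called genes with a mean of at least 5 CPM in the higher group and every library of a group on the same side of the other group's median. That last condition was dropped for the differences between effects. Predicted genes, pseudogenes, ribosomal, mitochondrial, haemoglobin, immunoglobulin and T cell receptor genes, Xist and Y-linked genes were left out of these extremes. Up to 4 called members per list with the smallest p were added, and the 6 highest and 6 lowest genes that ASO1 moved back. For a group with 0 reads the fold was bounded with 3 reads over the group. Counting error alone enters that bound. Of the 193 named genes, 14 have an exon overlap with a tested gene on the opposite strand (Alas2, Dbp, Ddit3, Dusp1, Elovl1, Eng, Ltbp3, Nefl, Nefm, Nox1, Plin4, Srebf1, Tagln and Ube2c), and their levels are uncertain because the strand setting is not given.

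The procedure was tested on simulated counts with 200 changed genes, 100 at 2-fold and 100 at 4-fold. edgeR recovered 38% of the 2-fold and 72% of the 4-fold changes in ASO1 against PBS in c22, 35% and 71% in c22 against wild type at 15 weeks, 10% and 62% at 5 weeks, 33% and 80% in ASO1 against PBS in wild type, and 18% and 52% in the difference between the ASO1 effects. It recovered 38% and 74% in c22 given ASO1 against wild type given PBS. For age it recovered 41% and 76% in c22, 12% and 50% in wild type, and 4% and 40% in the change of the genotype difference. Other splits of the libraries were refitted 100 times per contrast, the real split included.

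Alternatives planned before the data were examined were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma voom with sample weights, only the groups in the contrast, a replicate block, an adjusted p under 0.01, a 2-fold minimum, the other list tests, and leaving out each library. Alternatives added after seeing the data used Ddx3y, a Y-linked gene, and 10 liver genes. Libraries were classed as high in Ddx3y above 40 CPM and low under 10 CPM, and as holding liver transcripts above 10 CPM over the liver genes. These limits, the limit of 4000 CPM over 5 skeletal muscle genes, a minimum depth and the restriction to protein-coding genes were also set after seeing the data. The planned covariate on Xist was not run, since the tables used here hold 0 Xist transcripts.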

Results

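Antisense oligonucleotides against PMP22 were given to C22 mice, and the libraries address which transcripts of the sciatic nerve differ between C22 and wild type mice, and which of them change with treatment. The nerve holds myelinating and non-myelinating Schwann cells, axons, fibroblasts, macrophages, endothelium and fat. The labels name separate samples and not the sex of the mice. Ddx3y was above 40 CPM in all 8 c22 libraries given ASO1, in 4 of 8 given PBS and in 4 of 8 at 5 weeks, and under 10 CPM in all 19 wild type libraries. Liver transcripts were present in 4, 3 and 3 of those c22 groups and in 0 wild type libraries. The sum of 10 liver genes reached 6472 CPM in c22 ASO1 replicate 1.

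**Figure D1:**
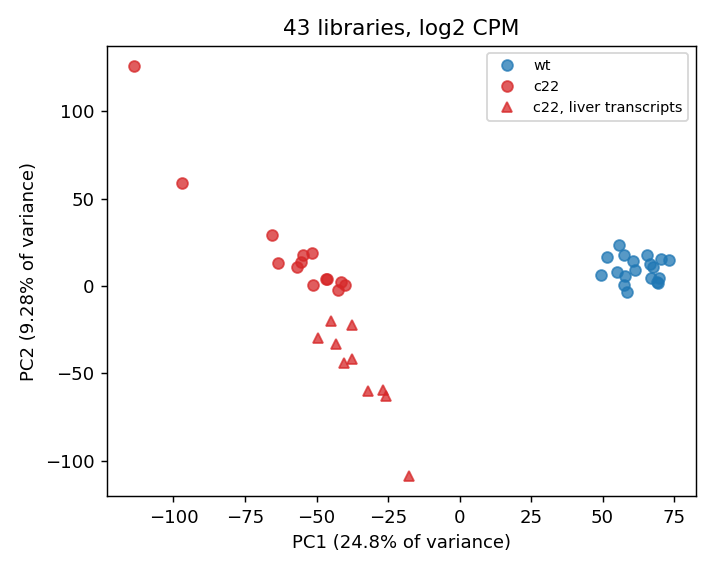
Principal components of log2 CPM over 43 libraries, with component 1 (24.8% of the variance) on the horizontal and component 2 (9.28%) on the vertical axis. Each point is a library, blue for wild type and red for c22, and triangles mark the 10 c22 libraries with liver transcripts. The genotypes separate on component 1, and the triangles lie at the lower values of component 2 among c22 libraries.

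Pmp22 (ENSMUSG00000018217, GRCm38 chromosome 11, 63128982 to 63159547), the target of the oligonucleotide, encodes a membrane protein of compact myelin. The reads were assigned to mouse transcripts, so human PMP22 enters only where it matches the mouse sequence, and the gene's level may mix both or hold the mouse gene alone. It stood at 5816 CPM ± 674 (SD, n = 8) in c22 and 3138 ± 519 (n = 3) in wild type at 5 weeks, a log2 difference of 0.89 (SE 0.29, adjusted p = 0.02) that no longer passed without wild type 5-week replicate 1 (0.76, adjusted p = 0.13) or 2 (0.86, adjusted p = 0.083). At 15 weeks it was 3515 ± 1488 in c22 given PBS and 2932 ± 842 in wild type given PBS (log2 difference 0.26, SE 0.21, adjusted p = 0.34). With ASO1 the means were 2179 ± 534 in c22 and 2052 ± 372 in wild type (n = 8 each). The log2 difference to PBS was -0.69 in c22 (SE 0.21, unadjusted p = 0.0016, adjusted p = 0.065) and -0.51 in wild type (SE 0.21, unadjusted p = 0.016, adjusted p = 0.51), so neither passed the test over all genes. The effects of ASO1 in the genotypes did not pass a test of their difference (-0.18, SE 0.29, adjusted p = 0.93). Without c22 PBS replicate 4 the c22 difference was -0.78 and passed. It was -1.05 within c22 libraries with liver transcripts and -0.39 in libraries free of them, and passed in neither.

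**Figure D2:**
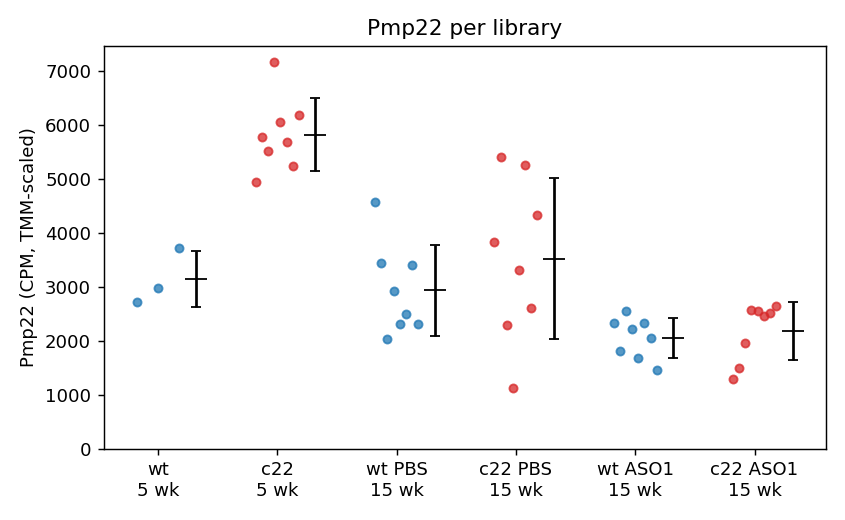
Pmp22 in TMM-scaled CPM (vertical axis) for each library of the 6 groups (horizontal axis), blue for wild type and red for c22, with the group mean and SD beside the points. The c22 libraries at 5 weeks lie between 4945 and 7156 CPM, and the c22 ASO1 libraries between 1281 and 2641 CPM.

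Genes called between wild type and c22 nerves given PBS at 15 weeks included members of the myelin, cholesterol synthesis and interferon-stimulated lists. They also included Pou3f1, a transcription factor gene of Schwann cells. Camera called these lists with the preset correlation but not with an estimated one, and genotype goes with the run of title numbers. Of 14712 genes, 2760 were higher and 2476 lower in c22. Myelin-membrane genes were mostly higher, with 15 of 22 higher and 2 lower. They included Cldn19, a claudin of Schwann cell tight junctions (log2 1.88, SE 0.20, adjusted p = 1.2e-10), Ncmap (2.04, SE 0.22), Pllp, or plasmolipin (2.54, SE 0.29), and Gjc3 (1.24, SE 0.18). Adjusted over the list alone the myelin counts were 15 higher and 3 lower. The list was called by camera (adjusted p = 0.0024) but not with an estimated correlation (adjusted p = 0.78 with an estimated correlation). The median over the list was 0.84. It was larger with only low-Ddx3y c22 libraries, matching the low wild type ones (20 of 22 genes positive, adjusted p = 1.4e-08, adjusted p = 0.29 with an estimated correlation). It was 1.07 with Ddx3y as covariate (adjusted p = 1.6e-06, adjusted p = 0.28 with an estimated correlation). With only high-Ddx3y c22 libraries it was 0.61, and camera did not call the list (adjusted p = 0.098).

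Cholesterol synthesis went the other way, with 12 of 24 genes lower and 2 higher in c22 (14 and 2 adjusted over the list alone, list adjusted p = 6.4e-05, adjusted p = 0.26 with an estimated correlation). Fdps fell by 1.71 on the log2 scale, Hmgcs1 by 1.88 and Stard4 by 1.89, while Mvd (1.01) and Tm7sf2 (1.05) were higher. Fatty acid synthesis genes divided evenly, with 4 higher and 4 lower of 16 (also adjusted over the list alone). Elovl6 was lower (-1.22) and Elovl1 higher (1.21).

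Pou3f1, a transcription factor of promyelinating Schwann cells, averaged 397.4 CPM ± 165 in c22 and 17.2 ± 4.1 in wild type (n = 8 each, log2 4.52, SE 0.28, adjusted p = 1.3e-17). Sox4 (2.08), Id2 (1.83) and Mcam (2.29) of the immature and injury-associated Schwann cell list were also higher, making 7 higher and 3 lower of 19 (7 and 4 adjusted over the list alone). That list was not called (adjusted p = 0.17). Jun averaged 137.9 CPM ± 37.3 in c22 and 140.6 ± 42.4 in wild type, and Ngfr 71.4 ± 23.9 and 49.2 ± 22.5 (n = 8 each). Neither passed (Jun -0.03, adjusted p = 0.93, Ngfr 0.54, adjusted p = 0.097). Of 8 non-myelinating Schwann cell genes Cadm1 was higher (1.35) and Scn7a and Ncam1 lower (-0.82 and -0.86), the same counts adjusted over the list alone.

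Interferon-stimulated genes were lower, with 10 of 22 lower and 1 higher (11 and 1 adjusted over the list alone, list adjusted p = 0.0024, adjusted p = 0.48 with an estimated correlation). Examples are Xaf1 (-3.11, SE 0.25), Ifih1, a sensor of double-stranded RNA (-2.93, SE 0.54), and Rsad2 (-1.77, SE 0.36). Cd163, a scavenger receptor of tissue macrophages, averaged 32.4 CPM ± 23.2 in c22 and 211.5 ± 65.7 in wild type (log2 -2.70, SE 0.39, adjusted p = 5.7e-07). It was among 4 lower and 0 higher of 22 macrophage genes by edgeR, where the list was not called (adjusted p = 0.19). T cell genes Cd3d (-2.42) and Cd4 (-2.29) were lower, as were 5 of 10 lymphocyte genes, and 5 of 10 adjusted over the list alone. The integrated stress gene Ddit3 (2.27) and the ATF4 targets Psat1 (1.12) and Shmt2 (2.09) were higher, with 5 of 16 ATF4 targets higher (6 higher and 2 lower adjusted over the list alone, adjusted p = 0.56). Of 12 p53 targets 5 were higher by both counts, among them Aen (1.17), Zmat3 (0.90) and Mdm2 (0.59), and that list was not called either (adjusted p = 0.18). The pericyte gene Rgs5 (-1.87), the endothelial gene Pecam1 (-1.51) and the neurofilament gene Nefm (-2.63) were lower, and Eng (2.27) and the tubulin gene Tubb3 (2.24) higher.

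The largest differences were in genes with few or 0 reads in a genotype. Dbp, a clock-controlled transcription factor, averaged 207.3 CPM ± 115.2 in c22 and 0.43 ± 0.60 in wild type. Zfp457 (log2 6.97, SE 0.52) and Tmem170 (6.41, SE 0.61) were higher in c22. Nanp was at least 92.2-fold, Isoc2b at least 60.0-fold, Nox1 at least 39.4-fold and Tigd5 at least 39.2-fold higher, with 0 reads in wild type given PBS. Uox, an enzyme abundant in liver, averaged 7.73 CPM in c22 and 0.133 CPM in wild type. Adm, the vasodilator adrenomedullin, was at least 763-fold and Glycam1 at least 313-fold lower in c22, with 0 reads there. Ces5a (-5.90), Myo7a (-4.94), the glutamate decarboxylases Gad2 (-4.53) and Gad1 (-4.52), Aloxe3 (-4.52) and the neurotrophin Ntf5 (-4.51) were also lower. With only low-Ddx3y c22 libraries 4159 genes were called, and with only high-Ddx3y ones 3582. With only liver-positive c22 libraries 3519 were called and with liver-free libraries 5010. Genotype goes with the run of title numbers, and these cannot be told apart.

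The other lists were not called at 15 weeks between the genotypes. By edgeR the counts of higher and lower members, then adjusted over the list alone, were 0 and 1 of 8 mast cell genes (0 and 1, adjusted p = 0.6), 3 and 5 of 20 fibroblast and matrix genes (3 and 5, adjusted p = 0.68), 0 and 2 of 14 adipocyte genes (0 and 1, adjusted p = 0.18) and 0 and 1 of 14 skeletal muscle genes (0 and 0, adjusted p = 0.65). They were 2 and 3 of 12 endothelial genes (2 and 3, adjusted p = 0.49), 0 and 5 of 11 pericyte and smooth muscle genes (0 and 5, adjusted p = 0.12), 0 and 1 of 8 perineurial cell genes (0 and 0, adjusted p = 0.53) and 2 and 2 of 8 neuron and axon genes (2 and 3, adjusted p = 0.49). Cell cycle genes had 2 and 3 of 18 (2 and 3, adjusted p = 0.49), unfolded protein response genes 3 and 2 of 15 (3 and 2, adjusted p = 0.49), immediate early genes 1 and 1 of 9 (3 and 2, adjusted p = 0.85) and red blood cell genes 1 and 0 of 5 (0 and 0, adjusted p = 0.62). The fibroblast list (median 0.09) and the endothelial list (median 0.02) had a positive median and a test that pointed down.

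At 5 weeks, before any dosing, called cholesterol synthesis genes were lower in c22 than in wild type, and called myelin-membrane and immature Schwann cell genes mostly higher. Camera called these lists with the preset correlation but not with an estimated one. Genotype goes with the run of title numbers at this age too. Here 1849 genes were higher and 2054 lower in c22. Of 24 cholesterol synthesis genes 13 were lower and 0 higher by edgeR (14 and 0 adjusted over the list alone, list adjusted p = 2.4e-06, adjusted p = 0.076 with an estimated correlation). Fdps fell by 2.20 and Mvk by 1.58. Of 22 myelin genes 10 were higher and 3 lower by both counts, with Cldn19 at 1.97, Pllp at 2.09 and Drp2, a dystroglycan-complex protein, at -2.26 (list adjusted p = 0.0067, adjusted p = 0.51 with an estimated correlation).

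Immature and injury-associated Schwann cell genes were called at this age, with 7 higher and 2 lower of 19 (8 and 2 adjusted over the list alone, list adjusted p = 0.0067, adjusted p = 0.076 with an estimated correlation). Pou3f1 averaged 433.5 CPM ± 142.1 in c22 and 24.3 ± 3.2 in wild type (log2 4.15), and Id2 (2.86) and Mcam (4.27) were higher. The neurotrophin receptor gene Ngfr averaged 143.4 CPM ± 18.3 in c22 and 39.7 ± 10.5 in wild type (log2 1.85, SE 0.38, adjusted p = 0.00025), and Jun 224 ± 41.3 and 120.9 ± 12.1. Lymphocyte genes were lower, 6 of 10 over all genes and 9 adjusted over the list alone (list adjusted p = 0.0067, adjusted p = 0.46 with an estimated correlation), with Cd79a, a B cell receptor gene, at least 65.7-fold lower. Interferon-stimulated genes were lower in 5 of 22 by both counts (list adjusted p = 0.0095, adjusted p = 0.47 with an estimated correlation). Adipocyte genes were lower in 3 of 14, or 2 adjusted over the list alone (list adjusted p = 0.033, adjusted p = 0.69 with an estimated correlation), with Lpl at -2.29. Cd163 averaged 40.5 CPM ± 17.9 in c22 and 211.7 ± 23.3 in wild type. Dbp averaged 262.6 CPM in c22 and 0.211 CPM in wild type. Nanp (at least 49.2-fold), Marveld3 (40.6-fold at least) and Isoc2b (at least 26.9-fold) were higher, and Glycam1 (at least 554-fold) Pakap (at least 165-fold) and the macrophage receptor gene Marco (-6.57) lower. The immediate early gene Fos was higher (4.11, SE 0.83), and Nefm (-3.24) and Stmn2 (-1.94), both neuronal, were lower. Skeletal muscle genes were higher in 14 of 14 at a median of 4.33, with 0 called by edgeR and the list not called (adjusted p = 0.19). The sum of 5 muscle genes was 5722 CPM ± 8952 (n = 8) in c22 and 331.7 ± 418.7 (n = 3) in wild type, and in libraries low in muscle transcripts 3238 genes were called. There the medians were -0.73 for cholesterol synthesis (adjusted p = 3.2e-06), 0.77 for myelin (adjusted p = 0.0022) and 0.96 for the injury list (adjusted p = 0.0022). These adjusted p are from camera with the preset correlation, and in all libraries none of these lists was called with an estimated one. Called genes numbered 2495 without wild type 5-week replicate 1. Called at both ages in the same direction were 2872 genes, and 1 in opposite directions.

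In c22 nerves given ASO1, cholesterol synthesis genes were higher, and several genes of immature, injury-associated and non-myelinating Schwann cells lower, than in c22 nerves given PBS. Of 14712 genes 93 were higher and 214 lower with ASO1, 108 and 161 under RLE scaling, 207 and 285 with DESeq2 and 169 and 346 with voom. With only high-Ddx3y c22 libraries 35 were higher and 21 lower. Of 24 cholesterol synthesis genes 10 rose and 0 fell by edgeR (17 and 0 adjusted over the list alone). The median log2 change over the list was 0.81, and the list was called with camera (adjusted p = 1.6e-27) and with an estimated correlation (adjusted p = 3e-06 with an estimated correlation). Sc5d rose by 1.54 (SE 0.17) and Fdps, which makes farnesyl diphosphate, by 1.15 (SE 0.19). Idi1 (1.27), Pmvk (1.15), Hsd17b7 (1.02), Cyp51 (0.98), Acat2 (0.92) and Mvd (0.88) rose as well. The median was 0.65 with only high-Ddx3y c22 libraries (5 of 24 called by edgeR), 0.57 with only liver-positive ones (2 of 24) and 1.00 in liver-free libraries (12 of 24). Of 16 fatty acid synthesis genes the desaturases Fads2 (1.73) and Fads1 (0.77) rose (2 higher, and 2 higher and 1 lower adjusted over the list alone), and that list was not called (adjusted p = 0.097).

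Of 19 immature and injury-associated Schwann cell genes 6 fell and 1 rose (7 and 1 adjusted over the list alone, list adjusted p = 0.00095, adjusted p = 0.015 with an estimated correlation). Jun, a transcription factor of the Schwann cell injury response, averaged 66.0 CPM ± 11 with ASO1 and 137.9 ± 37.3 with PBS (log2 -1.06, SE 0.18, adjusted p = 0.00047). Ngfr averaged 30.6 ± 15.0 and 71.4 ± 23.9 (log2 -1.22, SE 0.26, adjusted p = 0.0047), and Pou3f1 197 ± 78.5 and 397.4 ± 165 (log2 -1.01, SE 0.24, adjusted p = 0.014). Sox4 (-1.27), Id2 (-1.12) and Tnc, an extracellular matrix protein (-3.20), fell, and the trophic factor Cntf, which mature Schwann cells make, rose (1.01). Of 8 non-myelinating Schwann cell genes 3 fell by both counts, Ngfr, Chl1 (-0.76) and Cadm1 (-0.77) (list adjusted p = 0.0027, adjusted p = 0.015 with an estimated correlation). This list shares Ngfr, Gfap, Ncam1 and L1cam with the injury list, so the results of these lists are not independent. Without a filter on low counts, with 26 genes tested, the injury list lost the call with an estimated correlation (adjusted p = 0.099). With Ddx3y as covariate the injury and non-myelinating lists both lost that call (adjusted p = 0.061 and 0.077 with an estimated correlation). The injury list had a median of -0.42. With only high-Ddx3y c22 libraries it was -0.51, with 0 of 19 genes called by edgeR (adjusted p = 0.0021, adjusted p = 0.062 with an estimated correlation). With only liver-positive ones it was -0.31, again with 0 of 19 called by edgeR (adjusted p = 0.021, adjusted p = 0.28 with an estimated correlation). In liver-free libraries it was -0.58, with 3 lower and 1 higher (adjusted p = 0.0089, adjusted p = 0.11 with an estimated correlation). The non-myelinating list had a median of -0.40, and -0.40 with only high-Ddx3y c22 libraries, with 0 of 8 called by edgeR (adjusted p = 0.0083, adjusted p = 0.062 with an estimated correlation). With only liver-positive ones both tests called it, at a median of -0.42 with 1 of 8 lower (adjusted p = 4e-05, adjusted p = 0.0037 with an estimated correlation). In liver-free libraries the median was -0.43 and neither test called it, with 0 of 7 called by edgeR (adjusted p = 0.16, adjusted p = 0.45 with an estimated correlation).

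**Figure D3:**
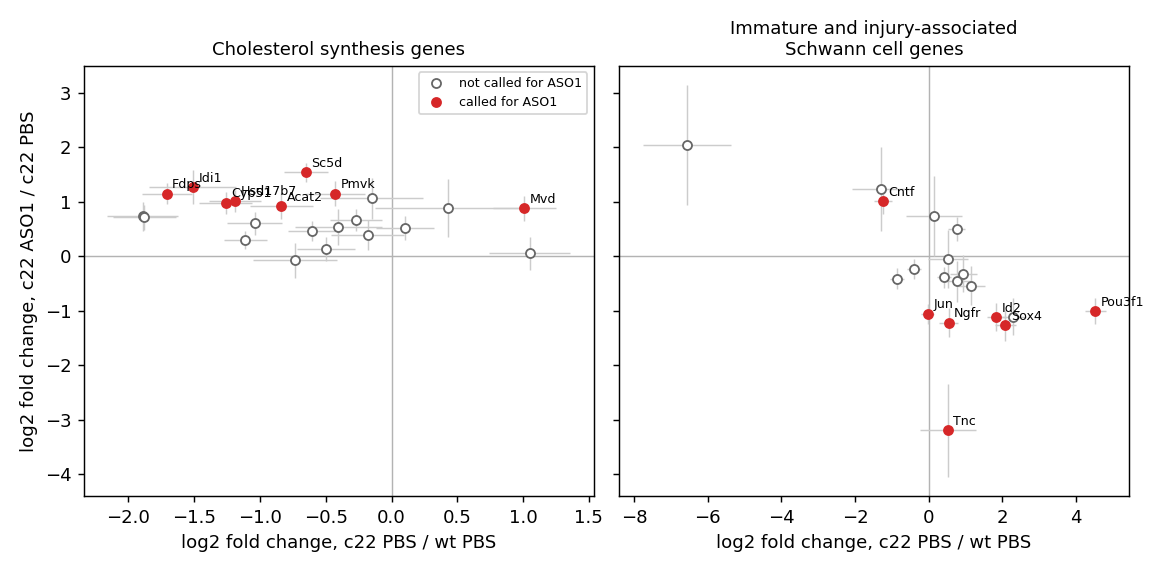
Log2 fold change with ASO1 in c22 (vertical axis) against log2 fold change of c22 over wild type given PBS (horizontal axis), for 22 of the 24 cholesterol synthesis genes (left, 2 not shown) and 19 immature and injury-associated Schwann cell genes (right). Points are genes, filled where called for ASO1, and bars are standard errors. Fdps lies at -1.71 and 1.15, and Pou3f1 at 4.52 and -1.01.

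Compact myelin genes were not called as a list with ASO1 in c22 (adjusted p = 0.15). Of 22 Ugt8a, which makes galactocerebroside, rose (1.25, SE 0.19) and Gjc3 (-0.88) and Gldn (-0.75) fell, also adjusted over the list alone. The median over the list was -0.26. With only liver-positive c22 libraries it was -0.36, and camera called the list lower (adjusted p = 0.00093, adjusted p = 0.5 with an estimated correlation). It was 0.16 with only high-Ddx3y ones (adjusted p = 0.17) and -0.07 in liver-free libraries (adjusted p = 0.98), where the list was not called. Interferon-stimulated genes were called as a list with 0 of 22 members called by edgeR over all genes and 0 adjusted over the list alone (adjusted p = 0.021, adjusted p = 0.48 with an estimated correlation). Fibroblast and matrix genes fell in 2 of 20, or 6 adjusted over the list alone (list adjusted p = 0.03, adjusted p = 0.5 with an estimated correlation), with Col5a1 at -1.04 and Col1a2 at -0.96. Saa3, an acute-phase protein (4.92, SE 1.1), Nts, or neurotensin (3.37, SE 0.93), Vnn1 (3.28), Fcna (2.77), the mesothelial gene Msln (2.51), Rspo1, a Wnt pathway agonist (2.00), and Zfp972 (1.96) were among the genes that rose most. Dlk1 (-3.77, SE 0.90), Gpc2 (-3.00), Cmtm2b (-2.89), Rab38 (-2.45), the chemokine Cxcl14 (-2.30), Ppp2r2c (-2.09) and Alpl, or tissue-nonspecific alkaline phosphatase (-1.99), fell most. The neuronal gene Stmn2 (1.20), the T cell gene Cd3d (1.39) and the amino acid transporter gene Slc7a5 (0.97) rose and the immediate early gene Nr4a1 fell (-0.99). Macrophage genes had 0 of 22 called by both counts (adjusted p = 0.27), and skeletal muscle genes a negative median (-0.34) with a test that pointed up (adjusted p = 0.7).

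The count of 307 depended on the libraries. It was 56 with only high-Ddx3y c22 libraries, 34 with only liver-positive ones, 368 in liver-free libraries and 95 with only the c22 PBS and ASO1 groups in the fit. Without c22 PBS replicate 6 it was 151, without c22 PBS replicate 8 it was 177 and without c22 ASO1 replicate 2 it was 195, and DESeq2 called 492 and voom 515.

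Of the 5236 genes that differed between c22 and wild type given PBS, ASO1 moved 160 back toward the wild type level in c22, a share of 3.06%, which is 52.1% of the genes it changed. Without c22 PBS replicate 6 the share was 1.77%, and within high-Ddx3y c22 libraries 0.782%. Of these, 108 were higher in c22 and fell and 52 were lower and rose, against 40.1 and 15.7 for independent lists. Moved further away were 11 and 20 genes, against 17.4 and 36. Among genes higher in c22, Tyrp1 (-2.84), Rit2 (-2.94), Cmtm2b (-2.89), Ppp2r2c (-2.09), Marveld3 (-1.93) and Piwil4 (-1.50) fell with ASO1. Among genes lower in c22, Rspo1 (2.00), Ifi205 (1.80), the macrophage lectin Mgl2 (1.32), Sema5a (0.89) and Hs3st4 (0.76) rose, and Il31ra averaged 1.71 CPM with ASO1 and 0.0514 CPM with PBS. Both contrasts use the c22 PBS libraries, which alone favours opposite signs, so the counts for independent lists are not a fair baseline. In random splits of the c22 PBS and ASO1 libraries with 65, 44 and 41 calls, 69.2%, 22.7% and 58.5% of the calls moved back. Chance is therefore not excluded for the part of 52.1%. Those splits placed 1 and 6, 6 and 1, and 2 and 5 liver-positive libraries on the sides, against 4 and 3 in the real one. They are therefore not a clean measure of chance. Across genes, which are not independent replicates, the log2 changes correlated at -0.13 (covariance -0.12), against -0.49 (covariance -0.16) in simulated unchanged groups. With the PBS libraries split, the correlations were 0.10 and -0.05, and 75 and 58 genes moved back against 9 and 15 moved further. Genotype goes with the run of title numbers, so differences between runs among the 5236 genes cannot be told apart from genotype. The share moved back and the count that still differed therefore do not measure how much of a genotype effect ASO1 reversed. Of the 5236 genes 3821 still differed in the same direction between c22 given ASO1 and wild type given PBS.

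That last comparison called 2638 genes higher and 2436 lower in c22 given ASO1. Cholesterol synthesis genes then stood at 6 higher and 5 lower of 24 (8 and 5 adjusted over the list alone), with Mvd (1.89) and Sc5d (0.89) above wild type and Hmgcs1 (-1.17) below. Pou3f1 remained higher (3.50, SE 0.27), and Jun (-1.09) and Ngfr (-0.68) were lower than in wild type. Myelin genes were higher in 8 of 22 and lower in 2 (9 and 2 adjusted over the list alone, list adjusted p = 0.0495, adjusted p = 0.99 with an estimated correlation), with Pllp at 1.96 and Drp2 at -1.48. Xaf1 (-3.36), Cd163 (-3.66), Mrc1 (-1.91), Rgs5 (-1.87) and Col3a1 (-1.74) were lower. The 4 highest genes were liver transcripts, Fabp1 (at least 544-fold), Fgb (505-fold at least), Apoa2 (at least 432-fold) and Slco1b2 (431-fold at least), with 0 reads in wild type given PBS. Only 4 of the 8 c22 ASO1 libraries held liver transcripts. The sum of 10 liver genes was 6472 CPM in replicate 1, against a group median of 331. Adm (at least 641-fold), Lrrc15 (-5.93) and Ces5a (-5.67) were the lowest, and Cd209f averaged 0.12 CPM against 6.38.

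In wild type nerves ASO1 changed 3 genes by edgeR, with 1140 at an unadjusted p under 0.05, 52 called by DESeq2 and 16 by voom. The count ran from 2 to 8 over leave-outs, with a move of more than 1.5 times without c22 PBS replicate 1, 2, 4, 5 or 7, c22 ASO1 replicate 2, 3 or 4, wild type PBS replicate 7, or wild type ASO1 replicate 1, 2 or 3. Cd163 fell from 211.5 CPM ± 65.7 to 34.2 ± 12.3 (n = 8 each, log2 -2.61, SE 0.39, adjusted p = 0.00071). Ubxn1 rose (1.09, SE 0.21, adjusted p = 0.023), and the pseudogene-type Gm3851, named here because only 3 genes were called, fell. In c22, where Cd163 was already low, it averaged 16.7 CPM ± 11.8 with ASO1 and 32.4 ± 23.2 with PBS. Cholesterol synthesis genes had a median log2 change of -0.03 in wild type, with 0 of 24 called over all genes and 0 adjusted over the list alone by edgeR. Macrophage genes (1 of 22 lower by both counts, adjusted p = 0.041, adjusted p = 0.74 with an estimated correlation), fibroblast and matrix genes (0 of 20 over all genes, 1 higher and 1 lower adjusted over the list alone, adjusted p = 0.007, adjusted p = 0.57 with an estimated correlation) and immediate early genes (0 of 9 by both counts, adjusted p = 0.028, adjusted p = 0.2 with an estimated correlation) were called lower as lists. Neuron and axon genes were called higher (0 of 8, and 1 adjusted over the list alone, adjusted p = 0.01, adjusted p = 0.2 with an estimated correlation).

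The effects of ASO1 differed between genotypes in 23 genes, 12 higher and 11 lower in c22, with 1271 at an unadjusted p under 0.05. Cholesterol synthesis genes rose more in c22, with 4 of 24 called (12 adjusted over the list alone, adjusted p = 2.7e-20, adjusted p = 7.3e-05 with an estimated correlation), among them Sc5d (1.52, SE 0.24), Hsd17b7 (1.37, SE 0.28) and Fdps (1.21, SE 0.26). Prdm1 (2.86), Zbtb16 (2.39) and Rspo1 (2.20) had the highest differences, and Rab38 (-3.53), Spock1 (-3.43), Ppp2r2c (-2.03) and Kcnj10, a glial potassium channel (-1.98), the lowest. The other lists called for this difference lost the call, with an adjusted p of 0.55 (myelin, lower), 0.17 (injury-associated and non-myelinating Schwann cells, lower), 0.41 (macrophages, lymphocytes and endothelium, higher), 0.39 (interferon, higher), 0.099 (unfolded protein response, lower) and 0.25 (immediate early, higher) with an estimated correlation. DESeq2 called 86 genes and voom 48. The count was 6 with only high-Ddx3y c22 libraries, 10 with only liver-positive ones and 75 in liver-free libraries. With only liver-positive c22 libraries the cholesterol list had a median of 0.56, against 0.89 in all libraries, and lost the call with an estimated correlation (adjusted p = 0.088 with an estimated correlation). The count ranged from 13 to 38 over leave-outs, and moved by more than 1.5 times without c22 PBS replicate 4, 6 or 8, c22 ASO1 replicate 3, 6 or 8, wild type PBS replicate 1, 2, 4, 5, 6 or 8, or wild type ASO1 replicate 1, 5 or 6.

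From 5 weeks to 15 weeks with PBS injections, some myelin and injury-associated Schwann cell transcripts were lower in c22 nerves over all libraries, and fewer injury genes were called in each subset of them. The comparison joins age with 9 weeks of injection. It called 187 genes higher and 127 lower. Mbp fell by 0.72 and Gldn by 0.77, and 3 of 22 myelin genes fell (4 adjusted over the list alone, list adjusted p = 0.0065, adjusted p = 0.57 with an estimated correlation). The median over the myelin list was -0.33. It was -0.04 with only low-Ddx3y c22 libraries, with 0 called by edgeR and the list not called (adjusted p = 0.71), and -0.19 with only liver-positive ones, with 0 called by edgeR and the list not called (adjusted p = 0.21). It was -0.43 with only high-Ddx3y ones (4 lower, adjusted p = 0.0021, adjusted p = 0.71 with an estimated correlation). By camera with the preset correlation, it was -0.37 in liver-free libraries (1 lower, adjusted p = 0.00061) and -0.25 in libraries low in muscle transcripts, with 0 called by edgeR (adjusted p = 0.0031). The chemokine Ccl2 (-2.96), Mcam (-1.47), Ngfr (-1.01) and Jun (-0.70) fell, with 4 lower and 2 higher of 19 (5 and 3 adjusted over the list alone), and that list was not called (adjusted p = 0.074). By edgeR 0 of 18 injury genes were called with only low-Ddx3y c22 libraries. Lower and higher were 1 and 1 with only high-Ddx3y ones, 1 and 1 with only liver-positive ones, 1 and 0 in liver-free libraries and 1 and 1 in libraries low in muscle transcripts. Pmp22 fell by 0.73 (adjusted p = 0.047), a call that 39 of the 43 leave-outs changed. Ces1f (2.74), Slc22a2 (2.53), Plk5 (2.44) and Flywch1 (2.39) rose. Adm was at least 263-fold lower at 15 weeks with 0 reads, Slfn4 fell by 6.12, and Dynlt1b (-4.68) and Ccl7 (-3.17) were lower at 15 weeks. Also called lower as lists were cholesterol synthesis (adjusted p = 0.032), interferon-stimulated (0.0072), fibroblast and matrix (0.032), skeletal muscle (0.032), unfolded protein response (0.012) and immediate early genes (0.011), and endothelial genes were called higher (0.0034). With an estimated correlation these had an adjusted p of 0.46, 0.34, 0.58, 0.72, 0.19, 0.19 and 0.34. The count of 314 was 3 with only low-Ddx3y c22 libraries, 301 with only high-Ddx3y ones, 103 with only liver-positive ones and 56 in liver-free libraries, and under RLE scaling 273 were higher and 118 lower. It was 193, 189 and 177 without c22 5-week replicate 1, 2 and 4, and 209, 529 and 181 without c22 PBS replicate 2, 5 and 7.

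Wild type nerves changed in 5 genes by edgeR over the same ages (n = 3 and 8), with 1210 at an unadjusted p under 0.05, 54 called by DESeq2 and 64 by voom. In simulated counts edgeR recovered 12% of 2-fold changes in this comparison, against 41% for age in c22. The counts of 5 and 314 genes therefore do not show that wild type changed less. The count of 5 ran from 1 to 8 over leave-outs and moved by more than 1.5 times without wild type PBS replicate 1 or 6 or wild type 5-week replicate 1 or 2. Ltbp3 rose (2.01, SE 0.35), and Ivl (-4.66), Ptma (-1.33) and Plekhg2 (-1.28) were among those that fell. Cholesterol synthesis genes were called lower as a list with 1 of 24 called and 2 adjusted over the list alone (adjusted p = 3.1e-05, adjusted p = 0.1 with an estimated correlation). The other 8 lists called lost the call with an estimated correlation. These were myelin (adjusted p = 0.017, then 0.71), lymphocyte (0.017, then 0.34), interferon-stimulated (0.026, then 0.51), fibroblast and matrix (0.0078, then 0.4) and unfolded protein response genes (0.0023, then 0.085), which were lower, and non-myelinating Schwann cell (0.017, then 0.1), mast cell (0.017, then 0.34) and skeletal muscle genes (0.017, then 0.85), which were higher. The genotype difference changed with age in 6 genes, with 1318 at an unadjusted p under 0.05, 77 called by DESeq2 and 23 by voom: Plk5 (1.95), Slc12a4 (1.86) and Slc23a1 (1.80) toward c22, and Nrep (-2.07), Smyd2 (-1.97) and Scarb2 (-1.19) the other way. This count ran from 1 to 9, and moved by more than 1.5 times without c22 5-week replicate 4, c22 PBS replicate 3, wild type PBS replicate 1, 2 or 7, or wild type 5-week replicate 1 or 2. Non-myelinating Schwann cell genes (0 of 8 by edgeR, 2 lower adjusted over the list alone, adjusted p = 0.0068, adjusted p = 0.062 with an estimated correlation) were lower among 5 lists called for that change. The others were injury-associated Schwann cells (lower, adjusted p = 0.017, then 0.12 with an estimated correlation), lymphocytes (higher, 0.032, then 0.59), skeletal muscle (lower, 0.0024, then 0.81) and immediate early genes (lower, 0.017, then 0.12).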

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

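The sets of genes tested for stray libraries, the sex and library-run tests of the genotype calls and the alternatives on Ddx3y and liver transcripts were chosen after their results were seen. The other tests here were written down first, except the comparison of the part of ASO1 calls that moved back with other splits. The bounds written down held no margin for spread (SE or SD). By those bounds alone, time of day for Dbp, and sex and liver transcripts for the injury-associated list, would have been excluded.

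The effect of ASO1 differed between c22 and wild type in a test of that difference for 23 genes. Prdm1 (2.86), Zbtb16 (2.39), Rspo1 (2.20), Sc5d (1.52), Hsd17b7 (1.37) and Fdps (1.21) were raised more in c22, and Rab38 (-3.53), Spock1 (-3.43), Ppp2r2c (-2.03) and Kcnj10 (-1.98) were moved the other way. The list tests of that difference called cholesterol synthesis (adjusted p = 2.7e-20), compact myelin (0.012), macrophage (0.012), interferon-stimulated (0.012), unfolded protein response (0.011), endothelial (0.017), immature and injury-associated Schwann cell (0.021), lymphocyte (0.021), non-myelinating Schwann cell (0.041) and immediate early genes (0.045). With an estimated correlation the cholesterol list alone was called (adjusted p = 7.3e-05 with an estimated correlation), and in liver-positive c22 libraries it was not (adjusted p = 0.088 with an estimated correlation).

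The genotype difference changed with age in 6 genes by a test of that change: Plk5 (1.95), Slc12a4 (1.86), Slc23a1 (1.80), Nrep (-2.07), Smyd2 (-1.97) and Scarb2 (-1.19). The list tests called skeletal muscle (adjusted p = 0.0024), non-myelinating Schwann cell (0.0068), immature and injury-associated Schwann cell (0.017), immediate early (0.017) and lymphocyte genes (0.032), and 0 of these with an estimated correlation, where the smallest adjusted p was 0.062.

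Single libraries lay far from the rest of their group for Pou3f1 in wild type ASO1 replicate 8 (45.2 CPM), Ngfr in wild type PBS replicate 1 (99.5 CPM) and Cd163 in c22 PBS replicate 4 (80.7 CPM). The gap to the nearest library was more than Dixon's 95% limit of the group's range. Of 45 group values tested 3 passed that limit, and chance gives about 1 in 20.

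Libraries were split 100 times per comparison, the real split included. Chance is argued against for the genotype count at 5 weeks (1 split as large, 3903 genes against at most 327 in another split). With 100 splits and no adjustment over the comparisons, it is not excluded. The same holds at 15 weeks (1, 5236 against 1516) and for ASO1 in c22 (1, 307 against 65). It also holds for c22 given ASO1 against wild type (1, 5074 against 1349). Another split called more genes than the real one for the difference between ASO1 effects (2, 23 against 29). So it was for age in c22 (3, 314 against 574). These numbers of splits are not adjusted over the comparisons, so chance is not excluded for either count. Nor can chance be excluded for ASO1 in wild type (12, 3 against 10) or age in wild type (17, 5 against 36). The same applies to the change of the genotype difference with age (5, 6 against 12). For the share moved back 1 split was as large (3.06% against 0.94%), but the share is bounded by the number of ASO1 calls, which was 0 in 86 of the 99 other splits, so this test adds nothing to that count. As a part of the ASO1 calls, 52.1% moved back, against 69.2% in the split with 65 calls, 22.7% in that with 44 and 58.5% in that with 41. Chance is not excluded for that part. Those splits were uneven in liver-positive libraries (1 and 6, 6 and 1, and 2 and 5 on the sides, against 4 and 3 in the real split). The splits of 574 and 455 genes for age in c22 placed all 6 libraries with liver transcripts on the same side, which points to a structure of the samples. Within liver-positive libraries 103 genes were called and in liver-free libraries 56. The split of 29 genes for the difference placed 1 and 6 liver-positive libraries on the sides, and the counts within were 10 and 75.

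The number of lists camera calls with the preset correlation was not shown to be beyond chance in any comparison. In wild type with age 2 splits were as large (9 lists against at most 9 in another split), not adjusted over the comparisons. The number of splits with as many lists was 23 for genotype at 5 weeks (6 lists, highest other 10), 71 at 15 weeks (3, highest other 10), 58 for ASO1 in c22 (5, highest other 12), 44 for ASO1 in wild type (4, highest other 10), 92 for c22 given ASO1 against wild type (1, highest other 8), 7 for the difference between ASO1 effects (10, highest other 11), 19 for age in c22 (8, highest other 11) and 42 for the change of the genotype difference (5, highest other 11). A list call by that test alone is therefore weak evidence in these libraries.

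Among the genotype calls at 15 weeks, 35.6% of the genes with no exon overlap on the opposite strand were called, so reads shared across strands are argued against as their cause. With only low-Ddx3y c22 libraries, matching the low wild type ones, 4159 genes were called, so sex is argued against for that number of calls. A difference between library runs stays open: all 19 wild type libraries had a larger share of reads in pseudogenes (at least 3.097%) than the highest c22 library (3.021%), and the title numbers follow genotype, so run, breeding and transgene cannot be told apart. Time of dissection is not decided for Dbp. Of 11 other clock genes 5 were called (Tef, Per1, Nr1d2, Per3 and Ciart, all higher in c22), fewer than the 9 that time of day was taken to need, and under the bound of 5.5 set for excluding it, but by less than the SD of such a count (1.66). Arntl and Per2 did not pass, and Dbp itself was near 0 in every wild type group (0.43 CPM or less on average). Strain variants near its 3′ end were not tested.

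For ASO1 in c22, the groups differ in Ddx3y, with 8 of 8 high with ASO1 and 4 of 8 with PBS. The cholesterol list kept a median of 0.65 (SE 0.13) within high-Ddx3y libraries, and its smaller median within or without liver transcripts was 0.57 (SE 0.135). These SEs are over the genes of a list and do not measure the spread between mice. Camera with an estimated correlation still called the list higher in high-Ddx3y and in liver-positive c22 libraries (adjusted p = 0.00019 and 0.025). Sex or liver transcripts alone are therefore argued against as its cause, but a part in its size is not excluded. For the injury-associated Schwann cell list the medians were -0.51 (SE 0.336) and -0.31 (SE 0.286), too wide a spread to exclude either, and sex, liver transcripts and treatment cannot be told apart there.

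Akap5, Lrrc17 and Elp6 took from 1.20% to 22.3% of the reads of a library. The share averaged 5.67% in c22 at 5 weeks, 10.38% with PBS and 15.32% with ASO1. In wild type it averaged 9.06% at 5 weeks, 13.87% with PBS and 12.27% with ASO1. Libraries over the median depth differed from the others by -0.852 percentage points (SE 1.46), with all groups pooled. Pooling does not separate depth from group, so depth is not decided. In c22 the shallowest library held the lowest share of its group (1.20% at 5 weeks, 1.85% with PBS, 10.7% with ASO1). In wild type the shallowest library lay above its group mean (10.3% at 5 weeks, 18.6% with PBS, 14.6% with ASO1). The BC1 RNA, which the tables used here do not hold, or its repeat, may be a source: other transcripts sharing 21-base words with it had a median correlation of 0.492 with the 3-gene sum, against -0.026 for transcripts of like abundance. The main transcripts of Akap5 and Elp6 share 57 and 51 of the 146 words of BC1 on the opposite strand. That of Lrrc17 shares 62 on the BC1 strand. The 7 other transcripts are too few to decide, and no biological explanation was tested.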

How the results depend on the processing

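The settings on Ddx3y, liver, muscle, depth and protein-coding genes were chosen after the data were seen, and the others before. Limits on Ddx3y, liver and muscle transcripts came from these libraries.

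Counts that moved by more than 1.5 times follow. With DESeq2, ASO1 in c22 gave 492, ASO1 in wild type 52, the difference 86, age in c22 800, age in wild type 54, the change of genotype with age 77 and the share moved back 4.67%. With voom these were 515, 16, 48, 696, 64, 23 and 4.91%. DESeq2 called unchanged genes at 11.9% of its calls in the simulated ASO1 comparison in c22. With only the groups in the contrast they were 95 for ASO1 in c22, 8 for ASO1 in wild type, 109, 9 and 1 for the age results and 1.52% moved back. At an adjusted p under 0.01, genotype at 5 weeks gave 2358, ASO1 in c22 94, the difference 10, the age results 81, 2 and 1, and the share 1.73%. With a 2-fold minimum, genotype at 15 weeks gave 3237, c22 given ASO1 against wild type 3081, ASO1 in c22 135 and age in c22 117.

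With Ddx3y as covariate ASO1 in wild type gave 8 and the share 1.68%. With the liver covariate ASO1 in wild type gave 12, the difference 52 and the age results 551, 10 and 20, and with both covariates 20 for ASO1 in wild type and 555, 12 and 18. Low-Ddx3y libraries gave 3 for age in c22 and 1 for the change with age. High-Ddx3y libraries gave 56 for ASO1 in c22, 6 for the difference, 16 for the change and 0.782% moved back. Liver-positive libraries gave 34, 10, 103 for age in c22 and 0.654%. Liver-free libraries gave 75 for the difference and 56 for age in c22. Low-muscle libraries gave 187 for ASO1 in c22, 9 for the difference, 99 for age in c22 and 0 for the change by edgeR. The estimated correlation called 4 of 198 list tests against 51.

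Pmp22 with ASO1 in c22 passed with DESeq2 (-0.65) and the liver covariate (-0.69). c22 given ASO1 against wild type passed in liver-positive libraries (-0.68). At 5 weeks it no longer passed in high-Ddx3y (0.87) or low-muscle libraries (0.80). Its fall with age in c22 no longer passed without a filter (-0.69), with only the groups (-0.70), in low-Ddx3y (-0.51), high-Ddx3y (-0.86), liver-positive (-0.51), liver-free (-0.86), deeper (-0.71) and low-muscle libraries (-0.63) or among protein-coding genes (-0.69). The difference between ASO1 effects changed sign in liver-free libraries (0.11).

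No pair of groups had every same-number correlation above 0.1 (closest, c22 PBS with c22 5 weeks, 0.095 to 0.45, with the best match of the same number in 2 of 8), so the numbers were not taken to pair samples. Between c22 groups the median same-number correlation was 0.15 (ASO1 with PBS), 0.23 (ASO1 with 5 weeks) and 0.23 (PBS with 5 weeks). For other pairs of libraries it was -0.046, -0.032 and -0.11. The best match had the same number in 4 of 8 for c22 ASO1 with c22 5 weeks. Liver transcripts were in replicates 1 to 3 of c22 at 5 weeks and given PBS, and 1 to 4 given ASO1. In c22 the numbers thus follow a structure of the samples. The replicate block gave 18 for age in wild type, 18 for the change with age and -0.75 for Pmp22 with age in c22, no longer passed.

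Changes of sign: with Ddx3y as covariate, Uox at 15 weeks (-0.0322) and, in c22 given ASO1 against wild type, Fabp1 (-35), Fgb (-11.4), Apoa2 (-29.5) and Slco1b2 (-21.2), none of which passed there (adjusted p = 1). Low-muscle libraries turned Lck (0.20) and Myh2 (0.48) in that comparison, and skeletal muscle genes with ASO1 in wild type (adjusted p = 0.018). Red blood cell genes turned with age in low-Ddx3y c22 libraries (adjusted p = 0.0066) and with ASO1 in liver-positive ones (0.025), and cholesterol synthesis with age in c22 in liver-positive ones (0.76). The cause was not tested.

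Leave-one-out ranges were 2495 to 4060 and 4850 to 5407 for genotype at 5 and 15 weeks, 151 to 364 for ASO1 in c22, 2 to 8 for ASO1 in wild type, 4678 to 5275 for c22 given ASO1 against wild type, 13 to 38 for the difference, 177 to 529, 1 to 8 and 1 to 9 for the age results and 1.77% to 3.91% moved back. The share was lowest without c22 PBS replicate 6. For Pmp22 they were 0.76 to 0.98 and 0.16 to 0.41 for genotype, -0.78 to -0.53 and -0.57 to -0.39 for ASO1 in c22 and wild type, -0.44 to -0.28 for c22 given ASO1 against wild type, -0.27 to -0.02 for the difference, and -0.82 to -0.57, -0.23 to 0.0225 and -0.72 to -0.46 for the age results. At 5 weeks the call was lost without wild type 5-week replicate 1 or 2. The planned covariate on Xist was not run, since 0 Xist transcripts are in the tables used here.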

Other observations

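Of 11 clock genes other than Dbp, 5 were called at 15 weeks, where 35.6% of all genes were called, and no enrichment was tested. At 15 weeks Tef averaged 840.7 CPM in c22 given PBS and 330.8 in wild type given PBS (log2 1.34, SE 0.21, adjusted p = 1.32e-06), Nr1d2 154.6 and 60.4 (1.34, SE 0.24) and Per1 72.8 and 19.3 (1.91, SE 0.32). Per3 (0.62) and Ciart (1.47) were higher too. Clock (0.14, adjusted p = 0.584), Arntl (-0.81, adjusted p = 0.303), Nr1d1 (0.28, adjusted p = 0.292), Per2 (0.42, adjusted p = 0.359), Cry1 (0.91, adjusted p = 0.328) and Hlf (-0.23, adjusted p = 0.46) did not pass. At 5 weeks Tef (1.04) and Nr1d2 (1.34) were called. ASO1 moved none of these 11 genes past the test by edgeR in c22 or in wild type, where 2071 and 1140 genes had an unadjusted p under 0.05, and DESeq2 and voom called 492 and 515 genes in c22 and 52 and 16 in wild type.

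Kcnj10, a glial potassium channel gene, was higher in c22 than in wild type at 5 weeks (2.88, SE 0.38) and at 15 weeks (2.13, SE 0.25), and after ASO1 it no longer passed against wild type given PBS (0.43, SE 0.25, adjusted p = 0.186). The fall with ASO1 in c22 was -1.70 (SE 0.24). The c22 libraries given ASO1 were all high in Ddx3y, and the count for the difference between ASO1 effects was 6 within high-Ddx3y c22 libraries.

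Pseudogenes made up 2.28% ± 0.31 (SD, n = 24) of reads in c22 and 3.66% ± 0.32 (n = 19) in wild type. Of the 305 pseudogenes called at 15 weeks 69 were higher and 236 lower in c22.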
